A study of Mus musculus with 86 samples.

How the data were processed

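The series holds 86 mouse samples: 26 RNA-seq libraries, 13 ChIP-seq libraries each for PU.1, H3K4me2 and H3K27ac, and 21 input libraries. Expression came as 4 deposited tables with 1 row per transcript. The gene signal in them was scaled by the authors to 10000000 mapped reads per library, per the file headers, which also give what 1 read is worth. STAR, Bowtie and HOMER and the mm10 genome build are named in the submitters' processing notes; versions are not given in the sources used here. The strand setting is not given either, so reads of overlapping and antisense genes cannot be told apart. Near-identical paralogs can share reads, and the beta globin genes carry identical values in pairs, Hbb-b1 with Hbb-bs and Hbb-b2 with Hbb-bt. PU.1 peaks and histone regions came as 1 list per sample, with a deposited score per entry that was used only to rank entries within a list. Coordinates are those of mm10 as listed.

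The tables were counted in 2 ways. In the tables of polyA libraries, replicates and strains, the listed length equals the full span of the transcript in 99.6% of rows, so introns were counted. In the table of ribosomal RNA-depleted cultures this holds for 8.26% of rows, so exons were counted. Values of the 2 kinds were never tested against each other. A freshly sorted LPM library counted over exons was not used here, so the planned test of cultured against freshly sorted LPM was not run, and cultured microglia were tested against the 1 freshly sorted microglia library in the same table. One row was kept per gene symbol, the one with the greatest listed length, which left 24063 symbols from 33072 rows.

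The values are whole multiples of 1 read, so reads were recovered by division: 100% of low values came out whole within a tolerance of 0.1. The design assumed counts and named this fallback for scaled values: limma with a mean-variance trend on log2(value + 1), with genes kept where at least 1 library reached 1. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 fold of at least 1. Folds are on the log2(value + 1) scale, which understates changes of low genes. edgeR's quasi-likelihood test on the recovered reads was added as an alternative after the values were seen. Error terms are standard errors of the log2 fold from limma, and means are given with standard deviations across libraries. The p-values measure the spread left after the terms of each fit. No population or treatment had 2 libraries within 1 table, strain or ligand, so this spread includes how a difference varies between them. In cultured microglia it includes the differences between cytokines. It may also be technical, since nothing in the labels says that replicates came from separate animals. BMDM and TGEM are exceptions by their values. Xist stood at 6418 in BMDM replicate 1 and 6.52 in replicate 2, and the Y gene Ddx3y at 2.28 and 2295. In TGEM replicates 1 and 2, Xist stood at 1.48 and 1738 and Ddx3y at 834.7 and 186.2. The replicates of each therefore differ in the sex of their animals, and the population fits had no term for sex.

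The 5 populations were fitted together on 10 C57BL6/J libraries, 2 per population, with the deposited table as a block, since per the labels replicate 1 was made from polyA RNA and replicate 2 by ribosomal RNA depletion (the kind is not given for replicate 2 of BMDM). Summed histone genes of replicate 2 of TGEM and BMDM (707.6 and 1264) lie within the range of the polyA libraries (602.9 to 2718), so the block stands for the table and not with certainty for the kind. A population's fold is the mean of its log values against the mean of the log values of the other 4. The strain fit used 6 libraries depleted of ribosomal RNA with the strain as a block. The strain table lists 0 reads on all 1047 X genes and 48 Y genes in its 4 libraries, so X and Y genes were left out of the strain fits. The planned tests of SPRET/EiJ and NOD/ShiLtJ against C57BL6/J were not run, because strain and table cannot be told apart there, and SPRET/EiJ was tested against NOD/ShiLtJ instead. The fit of cultured LPM used 8 libraries with terms for additive and ligand. In it limma found no gene-to-gene spread beyond the trend, so its p-values rest on a variance shared across genes along that trend. They do not measure the spread of each gene itself, for which 3 residual degrees of freedom were left. The other fits have 4 (populations), 2 (strains) and 2 (cultured microglia).

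Gene lists were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. The 25 lists were made before the data were examined: microglia markers, large peritoneal macrophage markers, small peritoneal macrophage and dendritic markers, elicited and cultured macrophage markers, core macrophage genes, retinoic acid response, TGF-beta response, immediate early and stress genes, inflammatory cytokines and NF-kB targets, interferon-stimulated genes, MHC class II presentation, cell cycle, complement, lipid and sterol handling, lysosome, extracellular matrix and adhesion, lineage transcription factors, and markers of neurons with astrocytes and oligodendrocytes, B cells, T and NK cells, mesothelium and fibroblasts, neutrophils, mast cells and eosinophils, erythroid cells and endothelium. The choices of design, alternatives and named-gene rule were also made before the data were examined. The rule names the 8 largest rises and 8 largest falls per comparison among called genes that changed the same way in every block and reach a mean of 5 in the higher group, leaving out small RNAs and clone names, the 4 largest changes of each list, and Gata6, Rarb, Sall1 and Spi1. The text gives those of them that bear on a comparison.

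Where every library of a group lists 0 reads for a gene, the fold is a lower bound that allows 3 reads per library. These bounds, and the intervals on shares of sites, cover counting error only. Sites were matched by an overlap of at least 1 bp. A site at a transcript start lies within 1000 bp of one. For genes near sites, the share of a population's genes with a site within 100 kb of the start was set against 10000 random lists of equal size drawn within 20 bins of mean expression. The deposited PU.1 list of TGFB1-treated LPM is identical to that of its vehicle and was not used. Motif content was not analysed here.

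The fits were tested on simulated data with 200 genes changed, 50 per fold. Changed genes were drawn only from those above a floor of mean expression. The random spread of each gene was estimated from the real libraries, but no effect of table, strain or ligand was simulated. The rates below therefore do not cover low genes or such effects. At folds of 2, 4, 8 and 64 the test of microglia against LPM called 2, 38, 82 and 100% of changed genes among 18880 genes, with 7 unchanged genes called. The strain fit called 4, 64, 96 and 100% among 18283, with 23 unchanged. ATRA called 38, 98, 100 and 100% among 15256, with 8 unchanged, and IL-34 called 40, 100, 100 and 100% among 15241, with 6 unchanged. With 1 freshly sorted library, the fit of cultured microglia called 0% of the 200 among 15710 genes; with 4000 genes changed, 1000 per fold, it called 0.1, 2.2, 11.8 and 55.3% among 15766, with 39 unchanged.

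Software was R 4.3.3, limma 3.58.1, edgeR 4.0.16, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.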

Results

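Macrophages of 5 kinds from C57BL6/J mice were profiled: microglia of the brain, large and small peritoneal macrophages (LPM and SPM), macrophages grown from bone marrow (BMDM) and macrophages drawn from the peritoneum by thioglycollate (TGEM). RNA was sequenced in 26 libraries. Of these, 10 are the 5 populations with 2 libraries each, 4 are microglia and LPM of NOD/ShiLtJ and SPRET/EiJ mice with 1 library per strain and population, and 1 is a further microglia library counted together with 11 cultures. The cultures were 3 of microglia, 1 per cytokine, and 8 of LPM, in which IL-34 or M-CSF was combined with all-trans retinoic acid (ATRA) or its vehicle DMSO, or with TGFB1 or its own vehicle. PU.1, H3K4me2 and H3K27ac were mapped by ChIP-seq, with 13 libraries each and 1 library per condition. The RNA samples of sorted populations were taken directly after staining and sorting, per the labels.

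Mapped reads ranged from 2890000 in SPM replicate 1 to 27000000 in TGEM replicate 1 (median 13355000 over the 26 libraries). TGEM replicate 2 held 4030000 and microglia replicate 3, which pairs with replicate 2 of the other populations, 6410000. Values are reads per 10000000 mapped reads, so 1 read is worth 0.3703 to 3.465. Between 13057 and 16673 gene symbols reached a value of 1 in a library. A shift common to most genes was measured as the median log2 fold of genes with a mean of at least 50. It was 0.86 between cultured and freshly sorted microglia, -0.28 for microglia against the other populations, 0.21 for BMDM, 0.15 for SPM and -0.20 for microglia against LPM, and at most 0.17 in size in the other comparisons. Changes are given relative to the mapped reads of each library.

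The comparison of microglia with LPM asked which genes separate the resident macrophages of brain and peritoneum (2 libraries each). The transcription factor genes Sall1 and Sall3 were among the largest rises in microglia. Sall1 (chr8 89027243 to 89044162, mm10) had a mean of 3437 ± 1660 (SD) in microglia and 9.82 ± 5.94 in LPM, a log2 fold of 8.34 ± 0.71 (SE, adjusted p = 4.31e-05, limma). Siglech (chr7 55768178 to 55778833) rose 605.7-fold from a background of 12.7 ± 11.4 in LPM (log2 9.24 ± 0.66, adjusted p = 1.81e-05). Nav3, Slco2b1 and the chemokine gene Ccl4 rose by log2 8.58 ± 0.58, 8.53 ± 0.54 and 8.43 ± 0.75, and the TGF-beta targets Smad7 and Pmepa1 by 6.62 ± 0.49 and 5.30 ± 0.50. In LPM, Gata6 (chr18 11052510 to 11085635) stood at 2135 ± 69.7 against 2.51 ± 3.55 in microglia, 870.7-fold higher (log2 fold -9.77 ± 0.71, adjusted p = 1.98e-05). The retinoic acid receptor gene Rarb (chr14 16430840 to 17082331) was 69.3-fold higher in LPM (adjusted p = 8.03e-06). Alox15, Vsig4, C4b and Cd36 fell in microglia by log2 -11.89 ± 1.39, -10.51 ± 0.72, -9.74 ± 0.84 and -8.31 ± 0.37. Spi1, which encodes PU.1, was not called (log2 0.17 ± 0.50, adjusted p = 0.887).

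**Figure D1:**
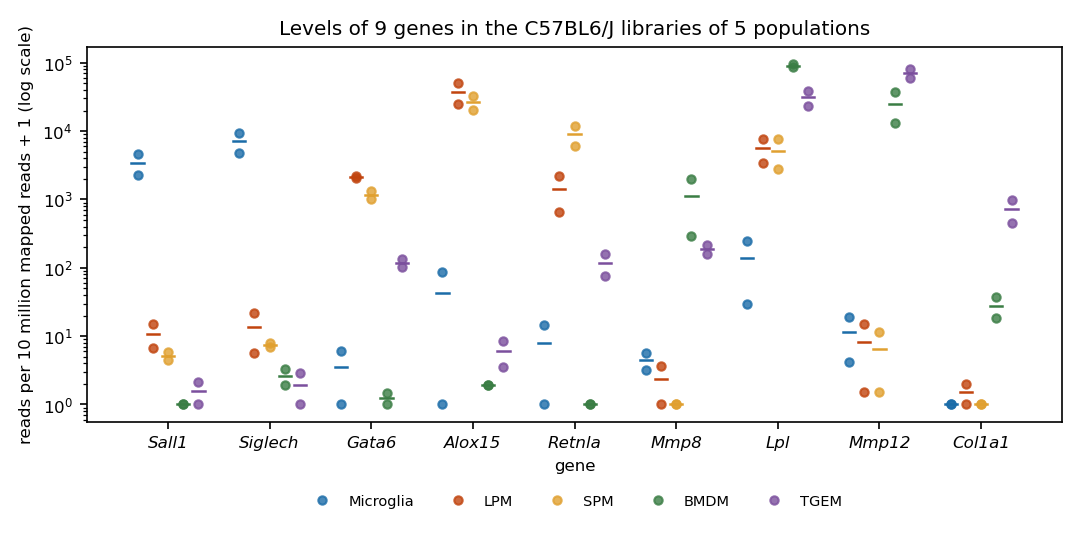
Value + 1 in reads per 10000000 mapped reads (log axis) of 9 genes in the 10 C57BL6/J libraries of 5 populations; points are libraries and bars are means. Sall1 and Siglech stood at means of 3437 and 7046 in microglia, and Gata6 at 2135 in LPM.

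The immediate early and stress genes formed a second large group. Fosb stood at 13800 ± 14600 in microglia and 46.4 in LPM (log2 8.00 ± 0.84, adjusted p = 0.000147), Jun rose 80.4-fold, and Egr1 by log2 6.34 ± 0.69. Of this list, 15 of 18 genes were called higher and 0 lower (16 and 0 adjusted over the list alone; camera adjusted p = 1.08e-15, and 0.188 with an estimated correlation). Cell cycle genes went down in microglia, with Top2a 46.4-fold lower and 14 of 20 called lower and 1 higher (17 and 1 adjusted over the list alone; camera adjusted p = 2.3e-08, and 0.357 with an estimated correlation). Mast cell genes were measured in LPM beside these: Cpa3 was 82.4-fold lower in microglia, and Cma1 and Tpsb2, at 0 in both microglia libraries, were at least 16.4-fold and 10.5-fold higher in LPM. B cell markers were lower in microglia in 6 of 8 cases (6 adjusted over the list alone; camera adjusted p = 0.000332, and 0.364 with an estimated correlation).

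Of 19313 genes tested, 1457 were higher in microglia and 2082 lower. Quantile normalization gave 1891 and 1930 (49.5% higher in place of 41.2%) and edgeR 1882 and 1956, so the excess of lower genes is not stable. The number called without LPM replicate 1 was 1375, without LPM replicate 2 it was 1694, and without microglia replicate 1 it was 2244. The genes given above with a fold kept their calls in every setting. Over all genes followed for this comparison, 299 values stayed and 49 no longer passed with 1 library left out, and 75 stayed and 12 no longer passed with no filter. Of 24 microglia markers, 23 were called higher (24 adjusted over the list alone; camera adjusted p = 1.26e-26, and 0.108 with an estimated correlation). Of 24 LPM markers, 22 were called lower in both counts (camera adjusted p = 2.61e-22, and 0.188 with an estimated correlation). No camera call of any comparison held with an estimated correlation, where the lowest adjusted p were 0.0771 and 0.0785.

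The remaining lists are given as genes called higher and lower in microglia over all genes, then adjusted over the list alone. SPM and dendritic markers had 1 and 12 of 18 (1 and 13), elicited macrophage markers 2 and 6 of 15 (2 and 6), core macrophage genes 5 and 4 of 18 (5 and 4), and retinoic acid response genes 2 and 9 of 18 (2 and 9). TGF-beta response genes had 8 and 5 of 22 (11 and 5), inflammatory cytokines 9 and 3 of 20 (9 and 3), interferon-stimulated genes 1 and 8 of 21 (1 and 8) and MHC class II genes 1 and 3 of 10 (1 and 3). Complement genes had 0 and 5 of 12 (0 and 5), lipid and sterol genes 1 and 9 of 20 (1 and 9), lysosome genes 3 and 0 of 19 (3 and 0) and matrix and adhesion genes 4 and 7 of 18 (5 and 7). Lineage transcription factors had 9 and 7 of 25 (10 and 8), and neuron, astrocyte and oligodendrocyte markers 2 and 1 of 12 (2 and 1). T and NK cell markers had 0 and 2 of 8 (0 and 3), mesothelial and fibroblast markers 1 and 0 of 10 (1 and 0), and neutrophil markers 4 and 1 of 8 (4 and 1). Mast cell and eosinophil markers had 0 and 6 of 10 (0 and 7), erythroid markers 0 and 0 of 7 (0 and 0) and endothelial markers 1 and 0 of 6 (2 and 0). With an estimated correlation these lists had camera adjusted p of 0.188 or more.

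Each population was next set against the mean of the log values of the other 4 (2 libraries against 8), to ask which genes lie above or below that mean. The same gene can therefore rise in several populations. In microglia, Siglech had a mean of 7046 against 5.41 elsewhere (log2 10.59 ± 0.52, adjusted p = 1.99e-06) and Sall1 of 3437 against 3.64 (log2 10.10 ± 0.56, adjusted p = 2.88e-06). Nav3 rose by log2 10.08 ± 0.46, Slc2a5 by 9.20 ± 0.66 and the matrix gene Sparc by 7.03 ± 0.44. Cd36 and Fabp4 fell by log2 -9.75 ± 0.29 and -9.74 ± 0.55. Fosb stood 389.7-fold and Egr1 83.9-fold above the other populations, and 17 of 18 immediate early genes were called higher (17 adjusted over the list alone; camera adjusted p = 2.93e-14, and 0.192 with an estimated correlation). All 24 microglia markers were called higher in both counts (camera adjusted p = 7.69e-23, and 0.143 with an estimated correlation). In all 2440 genes were higher in microglia, and 1427 without microglia replicate 1, with every gene given here with a fold kept.

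In LPM the phosphatidylserine receptor gene Timd4 led the genes that kept their calls, at 4860 ± 181 against 824.9 (log2 7.78 ± 0.46, adjusted p = 5.15e-05). The coagulation factor gene F5 rose by log2 7.72 ± 0.68, Wnt2 by 7.60 ± 0.58, C4b by 7.52 ± 0.67 and Thbs1 by 4.21 ± 0.34. Gata6 was 84.8-fold and Rarb 15.8-fold above the other populations (adjusted p = 0.000187 and 7.22e-05). Atp6v0d2, Itgax and Trem2 fell by log2 -6.75 ± 0.61, -5.24 ± 0.44 and -3.89 ± 0.25. LPM markers were called higher in 22 of 24 cases in both counts (camera adjusted p = 1.76e-26, and 0.188 with an estimated correlation), retinoic acid response genes in 8 of 18 with 1 lower (8 and 2 adjusted over the list alone; camera adjusted p = 0.0021, and 0.188 with an estimated correlation), and 7 of 19 lysosome genes were called lower (10 adjusted over the list alone; camera adjusted p = 2.9e-07, and 0.356 with an estimated correlation). Of the 1054 genes higher in LPM, 749 were also higher in SPM. The count was 111 without LPM replicate 1, 146 without LPM replicate 2, 602 without SPM replicate 1 and 627 without SPM replicate 2, and 545 with no filter on low values.

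In SPM, Timd4 also rose, to 3288 against 1218 (log2 7.08 ± 0.46, adjusted p = 9.17e-05), while Lhfpl2, Rgs1, Itgb5 and Trem2 fell by log2 -5.91 ± 0.27, -5.04 ± 0.31, -4.75 ± 0.33 and -3.44 ± 0.25. Retnla stood at 9036 ± 4253 against 385 (log2 8.32 ± 0.74, adjusted p = 0.000314) and the MHC class II gene H2-Eb1 at 4087 against 440.1 (log2 3.88 ± 0.36). SPM and dendritic markers were called higher in 16 of 18 cases (17 and 1 lower adjusted over the list alone; camera adjusted p = 2.39e-16), MHC class II genes in 9 of 10 (10 adjusted over the list alone; camera adjusted p = 1.9e-10) and LPM markers in 21 of 24 (21 and 1 lower adjusted over the list alone; camera adjusted p = 4.02e-20), each with an adjusted p = 0.165 with an estimated correlation. Markers of B cells were measured in the same libraries: Pax5 was 156.2-fold above the other populations, and all 8 B cell markers were called higher in both counts (camera adjusted p = 1.41e-10, and 0.165 with an estimated correlation). Of 1323 genes higher in SPM, 17 were called without SPM replicate 1, 357 without SPM replicate 2, 656 without LPM replicate 1, 741 without LPM replicate 2 and 594 with no filter. Without SPM replicate 1, which holds 2890000 mapped reads, Retnla, H2-Eb1 and Pax5 lost their calls and Timd4, Lhfpl2, Rgs1, Itgb5 and Trem2 kept them.

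In BMDM, grown in medium with M-CSF, Ms4a7 stood at 8459 against 172.2 (log2 7.99 ± 0.55, adjusted p = 6.27e-05), Mmp12 rose by log2 8.54 ± 0.81, Spp1 by 7.04 ± 0.58 and Nptx1 by 7.66 ± 0.49. Mmp12 and Spp1 also rose in TGEM, so they do not set BMDM apart from every other population. Retnla, Ptgis, Cxcl13 and Sall1 were at 0 in both BMDM libraries; SPM carry the mean of the others for Retnla (9036) and microglia for Sall1 (3437). C4b and Gata6 fell by log2 -8.38 ± 0.67 and -7.08 ± 0.56. Neutrophil markers were measured beside these: Mmp8 stood at 1125 against 47.7 and S100a9 at 277.5 against 22.2, and 7 of 8 were called higher (8 adjusted over the list alone; camera adjusted p = 2.32e-07). Cell cycle genes were higher in 10 of 20 cases (17 adjusted over the list alone; camera adjusted p = 1.5e-07), lipid and sterol genes in 9 of 20 (10 and 1 lower adjusted over the list alone; 1.91e-05) and lysosome genes in 8 of 19 (11 adjusted over the list alone; 7.24e-06); for these 4 lists adjusted p = 0.322 with an estimated correlation. Elicited macrophage markers had 9 of 15 higher and 2 lower (10 and 3 adjusted over the list alone; camera adjusted p = 9.63e-05, and 0.322 with an estimated correlation). Interferon-stimulated genes had 11 of 21 higher (15 and 1 lower adjusted over the list alone; camera adjusted p = 4.25e-07, and 0.327 with an estimated correlation). Of 1683 genes higher in BMDM, 229 were called without BMDM replicate 2, 829 without BMDM replicate 1, 829 without LPM replicate 2, 915 without LPM replicate 1, 930 without SPM replicate 1 and 1000 without SPM replicate 2; 850 were called with no filter and 1074 with the library kind as the block.

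In TGEM, Mmp12 reached 70590 against 6241 (log2 10.62 ± 0.81, adjusted p = 4.32e-05) and Gpnmb 273500 against 21910 (log2 9.91 ± 0.99, adjusted p = 0.000145). Atp6v0d2 rose by log2 8.96 ± 0.61, Spp1 by 6.59 ± 0.58, Fabp5 by 6.09 ± 0.37 and Cd63 by 5.49 ± 0.41. P2ry12 and Gpr34 fell by log2 -5.32 ± 0.31 and -6.82 ± 0.60, and Serpinb10 was at 0 in both TGEM libraries. Lysosome genes were called higher in 16 of 19 cases in both counts (camera adjusted p = 2.69e-09, and 0.356 with an estimated correlation), lipid and sterol genes in 14 of 20 with 2 lower in both counts (camera adjusted p = 4.65e-07, and 0.172 with an estimated correlation) and elicited macrophage markers in 11 of 15 (11 and 1 lower adjusted over the list alone; camera adjusted p = 1.72e-07, and 0.356 with an estimated correlation). Mesothelial and fibroblast markers were measured in the same libraries: Col1a1 stood at 719 ± 388 against 6.84 (log2 8.07 ± 0.60), Dcn and Wt1 rose by log2 7.79 ± 0.62 and 5.27 ± 0.67, and all 10 markers were called higher in both counts (camera adjusted p = 1.82e-08, and 0.136 with an estimated correlation). Of 2455 genes higher in TGEM, 715 were also higher in BMDM, and 1184 were called without TGEM replicate 2, which holds 4030000 mapped reads.

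Microglia and LPM of 3 strains were compared with the strain as a block (3 libraries each), to ask whether the difference holds across genetic backgrounds. Sall1 stood at 3206 ± 866 in microglia and 5.31 ± 1.23 in LPM (log2 8.97 ± 0.32, adjusted p = 6.86e-05), and Siglech rose by log2 8.65 ± 0.49. Nav3 rose by log2 8.64 ± 0.21 (adjusted p = 6.86e-05). Gata6 stood at 2032 ± 407 in LPM against 6.24 in microglia (log2 -8.76 ± 0.69, adjusted p = 0.000552), C4b fell by log2 -8.63 ± 0.61 and Rarb by -4.73 ± 0.57. The interferon-inducible gene Ifi203 fell by log2 -6.62 ± 0.30 (adjusted p = 0.000127), and 11 of 21 interferon-stimulated genes were lower in microglia with 1 higher (13 and 2 adjusted over the list alone; camera adjusted p = 1.98e-06, and 0.38 with an estimated correlation). Microglia markers were higher in 23 of 23 cases in both counts (camera adjusted p = 2.84e-24, and 0.38 with an estimated correlation) and LPM markers lower in 21 of 23 (camera adjusted p = 2.02e-17, and 0.38 with an estimated correlation). Spi1 was not called (log2 -0.32 ± 0.20, adjusted p = 0.343). Of 18496 genes outside the X and Y chromosomes, 1311 were higher in microglia and 1656 lower across strains. The number called was 310 without LPM replicate 2, 407 without LPM of NOD/ShiLtJ, 519 without microglia of NOD/ShiLtJ, 758 without microglia replicate 3, 1303 without LPM of SPRET/EiJ and 1897 with only the strain table. Rarb lost its call without each of LPM replicate 2, LPM of NOD/ShiLtJ, microglia of NOD/ShiLtJ and microglia replicate 3. The count was 17 with no filter on low values, where Nav3 and Ifi203 kept their calls and Sall1, Siglech, Gata6, C4b and Rarb lost them. The immediate early and stress genes, which stood out in the C57BL6/J microglia, had 2 of 18 called higher and 1 lower here in both counts (camera adjusted p = 0.173). The median log2 difference of the 18 genes between microglia and LPM was 3.45 and 3.24 in the C57BL6/J pairs, 0.15 in NOD/ShiLtJ and -1.62 in SPRET/EiJ. Averaged over the 18 genes, the C57BL6/J difference exceeded that of the other strains by log2 4.84. The SE of 0.38 is taken over the 18 genes, which are not independent replicates, so it does not measure the spread between pairs.

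**Figure D2:**
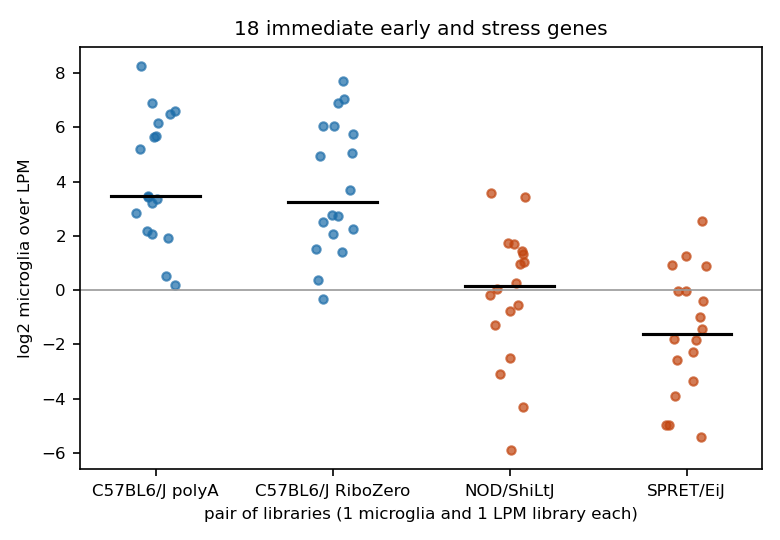
Log2 of microglia over LPM for 18 immediate early and stress genes in 4 pairs of libraries, each pair within its own table; points are genes and lines are medians. The medians were 3.45 and 3.24 in C57BL6/J, 0.15 in NOD/ShiLtJ and -1.62 in SPRET/EiJ.

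SPRET/EiJ and NOD/ShiLtJ were compared over microglia and LPM together (2 libraries each), and 22 genes were higher in SPRET/EiJ and 34 lower. Cwc22 stood at 12840 against 376.5 (log2 5.07 ± 0.29, adjusted p = 0.0059), and Slc14a2 rose by log2 6.49 ± 0.51. Slfn8 and Tns1 fell by log2 -6.94 ± 0.35 and -6.06 ± 0.34. Timd2 and Cxcl15, at 0 in both NOD/ShiLtJ libraries, were at least 31.6-fold and 22.8-fold higher in SPRET/EiJ. Gata6, Sall1 and Rarb were not called (adjusted p = 0.827, 0.918 and 0.896). None of these calls is stable: limma called 0 genes without microglia or LPM of SPRET/EiJ, without microglia or LPM of NOD/ShiLtJ, without LPM replicate 2 or microglia replicate 3 of C57BL6/J, and without the population block. edgeR on the recovered reads also called 0, while 2044 genes had an unadjusted p below 0.05 in limma with all libraries.

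Microglia cultured for 7 days with IL-34, M-CSF or GM-CSF (1 library each) were set against 1 freshly sorted microglia library, to ask what culture changes. The title of that library reads no treatment, but its column is headed Veh. It is of C57BL6/J mice, whose other microglia libraries held high immediate early and stress genes over LPM. Falls of these genes, Btg2 among them, therefore cannot be told apart from a raised level in the freshly sorted library. The freshly sorted library has no replicate and is assumed to vary like the 3 cultures, which differ in cytokine, so every p and standard error here carries that assumption. The scavenger receptor gene Cd36 stood at 5703 ± 834 (SD, n = 3) in culture and 3.35 before (log2 10.35 ± 0.24, adjusted p = 0.00529). Fabp5 and Lpl rose by log2 9.56 ± 0.35 and 8.92 ± 0.31, and the early response gene Btg2 fell from 8483 to 140.7 ± 13.1 (log2 -5.91 ± 0.17, adjusted p = 0.00529). Tmem119, P2ry12 and Sall1 fell by log2 -7.55 ± 0.37, -6.63 ± 0.48 and -4.25 ± 0.41, and Sall1 remained at 83.3 ± 21.9. Gpnmb, at 0 in the freshly sorted library, reached 49550 ± 24910, at least 14772-fold higher. Without the IL-34 culture, Tmem119, P2ry12 and Sall1 lost their calls (1121 to 1263 genes were called without any 1 culture); without the M-CSF culture Tmem119 did, and without the GM-CSF culture P2ry12, Sall1 and Gpnmb did.

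In all, 549 genes were higher and 933 lower in cultured microglia among 16446 tested, and edgeR called 255. The balance depended on the libraries and settings. Higher and lower were 45 and 1157 without IL-34, 121 and 1142 without M-CSF, 36 and 1085 without GM-CSF, and 527 and 271 with pseudocount 5. After quantile normalization, which removed the common shift of 0.86, 21.4% of called genes were higher in place of 37%. Microglia markers were lower in 8 of 24 cases (15 adjusted over the list alone; camera adjusted p = 4.36e-10, and 0.32 with an estimated correlation). Immediate early genes were lower in 8 of 18 (11 adjusted over the list alone; camera adjusted p = 1.18e-08, and 0.32 with an estimated correlation). Elicited macrophage markers were higher in 7 of 15 with 1 lower in both counts (camera adjusted p = 0.00132, and 0.371 with an estimated correlation) and lipid and sterol genes in 7 of 20 (12 and 2 lower adjusted over the list alone; camera adjusted p = 0.00103, and 0.32 with an estimated correlation). In the other C57BL6/J microglia libraries the immediate early genes stood above LPM by a median log2 of 3.45 and 3.24. In NOD/ShiLtJ and SPRET/EiJ the medians were 0.15 and -1.62. The fall of these genes in culture therefore cannot be told apart from a raised level in the freshly sorted library. Markers of other cells moved both ways. The neutrophil gene S100a9 stood at 57.02 in the freshly sorted library and at 0 in the cultures, at least 11.1-fold lower. The fibroblast genes Dcn, Col3a1 and Col1a2 each stood at 1 read in that library (1.118). They reached 94.2, 86.3 and 161.5 in the IL-34 culture and 202.4, 58.5 and 322.5 in the M-CSF culture, and no marker of the fibroblast list was called. The M-CSF culture stood apart in inflammatory genes looked up after the results were seen. Il1b was at 18935 in it against 28.0 with IL-34 and 629 with GM-CSF, Rsad2 at 62705 against 578.6 and 2432, Cxcl10 at 17890 against 37.0 and 608.8, and Nos2 at 2675 against 34.8 and 119.4. In the library titled GM-CSF, whose treatment field reads M-CSF, 375 genes stood at least 4-fold above both other cultures and 190 below; Ccl17 stood at 63.1 against 0 in both, and Cx3cr1 at 11.9 against 2192 and 1586, with no replicate. Dcn, Serpinh1 and Col4a2 were also at 0 in it, against 94.2, 106.5 and 71.8 with IL-34 and 202.4, 106.7 and 60.9 with M-CSF; Dcn is on the fibroblast list.

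ATRA was compared with DMSO in LPM cultured for 7 days (2 libraries each, 1 per ligand), to ask which LPM genes respond to retinoic acid. Cd5l rose from 76.9 ± 16.8 to 1313 ± 153 (log2 4.09 ± 0.33, adjusted p = 1.85e-31) and the retinoic acid hydroxylase gene Cyp26a1 from 41.6 to 578.4 ± 165 (log2 3.99 ± 0.46). Wnt2, Selp, F5 and C3 rose by log2 3.81 ± 0.47, 3.45 ± 0.44, 3.11 ± 0.38 and 2.58 ± 0.32. Gata6 rose 2.74-fold, from 68.1 ± 24.3 to 182.7 ± 1.7 (adjusted p = 0.00355). Cx3cr1 and Ms4a6b fell by log2 -2.66 ± 0.32 and -3.04 ± 0.37, and Rarb was not called (log2 0.17 ± 0.43, adjusted p = 0.999). LPM markers were higher in 14 of 23 cases with 1 lower (17 and 1 adjusted over the list alone; camera adjusted p = 4.29e-33, and 0.225 with an estimated correlation), complement genes in 4 of 12 (6 adjusted over the list alone; camera adjusted p = 2.28e-09, and 0.404 with an estimated correlation) and retinoic acid response genes in 2 of 15 (3 adjusted over the list alone; camera adjusted p = 0.000936, and 0.708 with an estimated correlation). Of 15417 genes, 301 were higher with ATRA and 54 lower, and edgeR called 259, of which 227 were the same. After quantile normalization 72.9% of called genes were higher in place of 84.8%. The calls are not stable: limma called 0 genes without the IL-34 culture with DMSO and 0 without the M-CSF culture with DMSO, against 1361 genes with an unadjusted p below 0.05 with all libraries. The prior degrees of freedom were infinite with all libraries and 4.2 and 2.1 without these, so the shared variance estimate changed along with the control. Cd5l in ATRA in cultured LPM stood at log2 4.46 ± 0.68 (adjusted p = 0.404) and 3.72 ± 0.81 (adjusted p = 0.213) there. The count was 27 without IL-34 with ATRA, 210 without M-CSF with ATRA, 145 without IL-34 with TGFB1 and 105 without M-CSF with the TGFB1 vehicle, and 154 without the replicate block. Gata6 lost its call without each of these 6 libraries, and Cyp26a1, Wnt2, Selp, F5 and C3 also without IL-34 with ATRA. With no filter 10 genes were called.

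TGFB1 was compared with its own vehicle in the same cultures (2 libraries each), to ask whether it moves LPM towards genes of microglia. Tmem119 rose from 7.05 ± 4.43 to 443.4 ± 113 (log2 5.88 ± 0.52, adjusted p = 1.38e-26) and Cx3cr1 from 406.7 ± 45.3 to 3573 ± 122 (log2 3.14 ± 0.32, adjusted p = 3.33e-20). Cspg4 and Spp1 rose by log2 7.70 ± 0.60 and 5.08 ± 0.32, and the TGF-beta targets Smad7 and Pmepa1 by 3.98 ± 0.36 and 3.29 ± 0.35. Timd4 fell from 393 ± 124 to 9.31 ± 3.23 (log2 -5.26 ± 0.34, adjusted p = 5.38e-51), and Emr4, Marco, Cxcl2 and Selp fell by log2 -7.42 ± 0.39, -6.23 ± 0.38, -5.13 ± 0.40 and -4.41 ± 0.44. P2ry12, Sall3 and Siglech were not called with TGFB1 (log2 0.54 ± 0.36, 1.61 ± 0.71 and 0 ± 0.72). Sall3 stood at a mean of 0 in the vehicle cultures, DMSO included. Sall1 was not tested, because it reached a value of 1 in none of the LPM cultures, those with TGFB1 included. Rarb was not called (adjusted p = 0.57), and nor was Gata6 (log2 0.86 ± 0.35, adjusted p = 0.153). With both vehicles pooled Gata6 in TGFB1 in cultured LPM passed, at log2 1.03 ± 0.28 and an adjusted p of 0.0119, where its alternatives ranged from 0.0101 to 0.855. Microglia markers were higher in 10 of 22 cases (12 adjusted over the list alone; camera adjusted p = 3.58e-14, and 0.0785 with an estimated correlation) and TGF-beta response genes in 13 of 22 with 1 lower in both counts (camera adjusted p = 4.6e-25, and 0.162 with an estimated correlation). Inflammatory genes were lower in 11 of 19 (12 adjusted over the list alone; camera adjusted p = 1.05e-20, and 0.162 with an estimated correlation), and cell cycle genes in 5 of 20 (10 adjusted over the list alone; camera adjusted p = 8.64e-08, and 0.582 with an estimated correlation). The endothelial genes Flt1 and Pecam1 rose by log2 5.19 ± 0.61 and 3.23 ± 0.54, while Cdh5 and Kdr were not called (adjusted p = 0.216 and 0.616). Endothelial markers were higher in 2 of 5 cases (3 adjusted over the list alone; camera adjusted p = 4.66e-06, and 0.162 with an estimated correlation). Of the genes tested, 489 were higher with TGFB1 and 544 lower, and edgeR called 953, of which 836 were the same. The order turned with other settings, to 517 and 455 after quantile normalization, 511 and 442 with edgeR and 632 and 516 with pooled vehicles. The count was 2 without the M-CSF culture with DMSO, 309 without M-CSF with the TGFB1 vehicle, 407 without IL-34 with TGFB1, 455 without M-CSF with TGFB1, 558 without IL-34 with DMSO and 564 without IL-34 with the TGFB1 vehicle. With no filter 8 were called. The genes given above as risen or fallen with TGFB1 lost their calls without M-CSF with DMSO and with no filter.

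ATRA and TGFB1 were then tested against each other, each relative to its own vehicle, and their effects differed in 732 genes. Marco went up by log2 2.13 with ATRA and changed by -6.23 with TGFB1, a difference of 8.35 ± 0.53 (adjusted p = 4.08e-51). Selp, Cyp26a1, Timd4 and C4b were on the same side, with differences of 7.86 ± 0.63, 6.95 ± 0.65, 6.75 ± 0.48 and 4.41 ± 0.47. Tmem119 and Cav1 were on the other side, at -5.17 ± 0.74 and -5.30 ± 0.47. Called in both comparisons but in opposite directions were 62 genes, 49 of them higher with ATRA and lower with TGFB1 against 10.6 for independent lists, and 65 genes were higher with both against 9.55. These overlaps need ATRA calls, of which limma made 0 without either DMSO culture, so they are not stable. The 732 genes were not tested with a library left out. The additives have separate vehicle cultures, and their log2 folds were uncorrelated across genes (Pearson r = 0.017, Spearman rho = 0.02; genes are not independent replicates).

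**Figure D3:**
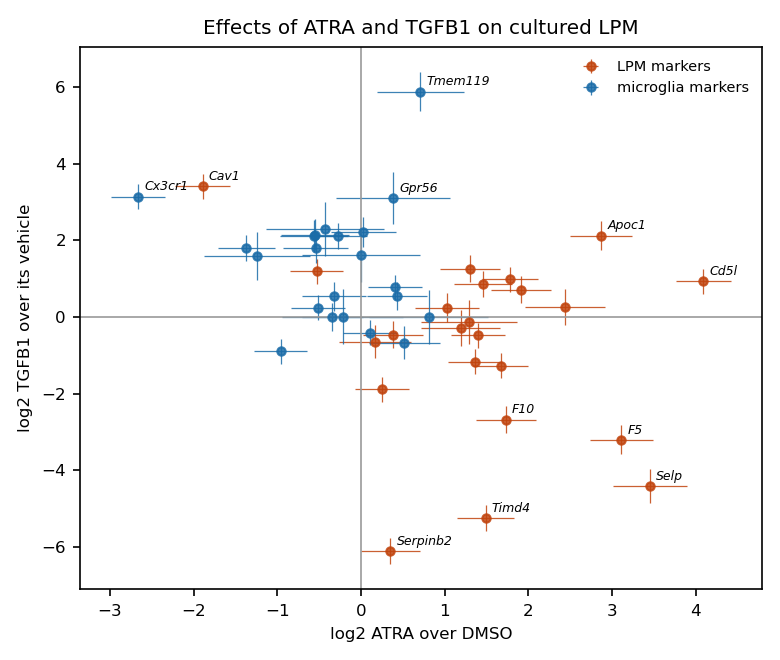
Log2 fold of ATRA over DMSO against log2 fold of TGFB1 over its vehicle in cultured LPM, for LPM and microglia markers with bars for the standard error. Selp lay at 3.45 and -4.41, and Tmem119 at 0.71 and 5.88.

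IL-34 was compared with M-CSF, the other ligand of the same receptor, in cultured LPM (4 libraries each, with the additive as a block). Haptoglobin (Hp) rose with IL-34 from 127.3 ± 40.1 to 587.7 ± 579 (log2 1.79 ± 0.23, adjusted p = 6.82e-11) and Il1b by log2 1.85 ± 0.41. Both moved most with ATRA, where Hp stood at 1439.8 with IL-34 and 87.4 with M-CSF and Il1b at 55.1 and 1.41. In the TGFB1 vehicle Hp stood at 205.4 and 160.7 and Il1b at 24.6 and 24.3. In DMSO both also stood higher with IL-34 than with M-CSF, so the vehicle cultures differ in this gap. The DNA replication and division genes Dtl, Cenpf, Rrm2 and Top2a fell by log2 -2.94 ± 0.43, -2.79 ± 0.40, -2.45 ± 0.40 and -2.08 ± 0.28, and 12 of 20 cell cycle genes were lower (13 adjusted over the list alone; camera adjusted p = 1.8e-33, and 0.356 with an estimated correlation). All these folds are pooled over additives, and for Rrm2 and Top2a the gap lay mostly in the vehicle cultures. Rrm2 stood at 0 with IL-34 and 68.2 with M-CSF in DMSO and at 5.94 and 61.1 in the TGFB1 vehicle, but at 17.81 and 19.02 with ATRA. Top2a stood at 18.3 and 346.9 in DMSO and at 127.2 and 115.5 with ATRA. Gata6 and Spi1 were not called (adjusted p = 0.816 and 0.849). In all 28 genes were higher and 126 lower. None of these calls is stable. With limma, which had 1217 genes at an unadjusted p below 0.05 with all libraries, 0 genes were called without the replicate block, 0 without IL-34 with DMSO, 0 without M-CSF with DMSO, 0 without M-CSF with the TGFB1 vehicle, 43 without IL-34 with TGFB1, 53 without IL-34 with ATRA, 55 without IL-34 with the TGFB1 vehicle, 0 with no filter, 26 after quantile normalization, where 61.5% were higher in place of 18.2%, and 15 with edgeR.

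The genes found higher in microglia or in LPM were followed as lists into the cultures. They were chosen on libraries of these populations, so the counts adjusted over the list alone are not independent evidence. In cultured microglia, 144 of 1403 microglia genes were lower and 11 higher (165 and 20 adjusted over the list alone; camera adjusted p = 1.52e-16, and 0.0771 with an estimated correlation), and 215 of 1907 LPM genes were higher and 37 lower (351 and 37 adjusted over the list alone; camera adjusted p = 1.22e-10, and 0.371 with an estimated correlation). With ATRA, 138 of 1974 LPM genes were higher and 14 lower (159 and 21 adjusted over the list alone; camera adjusted p = 0.0226, and 0.934 with an estimated correlation). With TGFB1, 178 of 1257 microglia genes were higher and 61 lower (201 and 70 adjusted over the list alone; camera adjusted p = 2.13e-07, and 0.582 with an estimated correlation), while 262 LPM genes were lower and 77 higher (318 and 92 adjusted over the list alone; camera adjusted p = 4.66e-06, and 0.772 with an estimated correlation). With IL-34, 79 LPM genes were lower and 10 higher (105 and 10 adjusted over the list alone; camera adjusted p = 0.0316, and 0.871 with an estimated correlation).

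The ChIP-seq lists asked which regulatory sites the populations share. They have no replicates, and scores are the authors' own. At Sall1, the microglia-only H3K27ac region with the highest score (3253.4) lay at chr8 89384442 to 89397784, 346.9 kb from the gene, and another (2994.5) at 89033816 to 89047561 overlapped it. Within 100 kb of Sall1, microglia had 8 PU.1 peaks, 13 H3K4me2 regions and 5 H3K27ac regions, and the other populations had none except 2 H3K4me2 regions in LPM. At Gata6, LPM had 17, 11 and 6 and SPM 13, 2 and 6, while microglia and BMDM each had 4, 2 and 0. An LPM-only H3K4me2 region lay within Gata6 at chr18 11054823 to 11060428 (score 451.2), and LPM-only H3K27ac regions lay at Wnt2 (chr6 18026134 to 18033059, 467.3) and Timd4 (chr11 46810015 to 46813671, 434.5). SPM-only H3K27ac regions with high scores lay at Bank1 (1263.4), a B cell gene, and Gimap7 (1129.6).

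Of 44869 PU.1 peaks in microglia, 22692 overlapped a peak in all 4 other populations, and 14.4% (95% interval 14.1 to 14.7) overlapped none. The share in no other population was 20.6% in SPM, with 89648 peaks, 10.7% in LPM, 14.2% in BMDM and 10.98% in TGEM. With lists of equal length the order turned: 28.2% in microglia and 7.83% in SPM. For H3K4me2 the shares ran from 12.2% in SPM to 18.7% in TGEM and for H3K27ac from 9.25% in LPM to 25.0% in TGEM. H3K4me2 of BMDM and TGEM was prepared with MNase and of the others with formaldehyde, and H3K27ac of BMDM and TGEM used another antibody supplier, so populations and protocol cannot be told apart there. The BMDM PU.1 sample carries an H3K4me2 entry in its antibody field. H3K4me2 regions shared by all populations lay at a transcript start in 61.5% of cases and microglia-only regions in 4.94%.

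**Figure D4:**
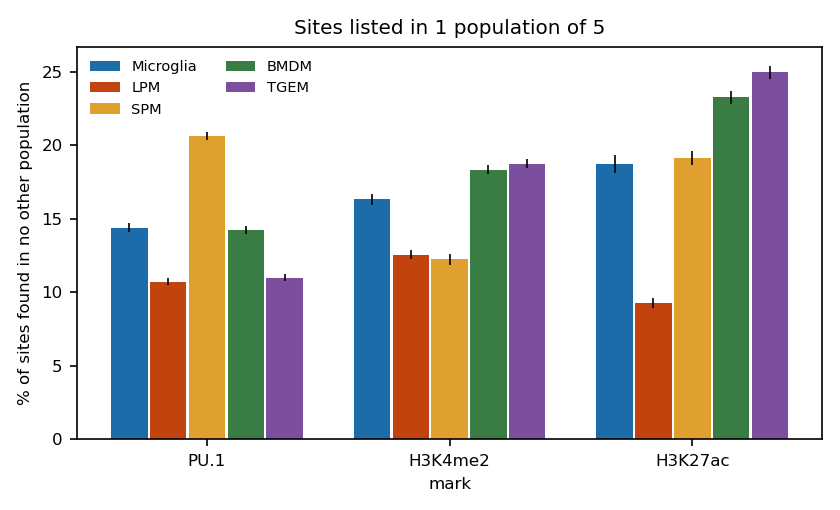
Percent of PU.1 peaks, H3K4me2 regions and H3K27ac regions of each of 5 populations that overlap an entry in no other population; bars are shares and lines are 95% intervals of counting error. PU.1 ranged from 10.7% in LPM to 20.6% in SPM.

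Genes higher in a population lay near its own sites more often than random genes of like expression, for every mark and population. Of the genes higher in microglia, 71.2% had a microglia-only PU.1 peak within 100 kb, against a mean of 53.9% (interval 52.1 to 55.7) over 10000 random lists, and 47.5% had a microglia-only H3K27ac region against 27.5%. Of the LPM genes 45.2% had an LPM-only H3K27ac region against 26.0%. The smallest excess was for H3K4me2 in TGEM, at 70.1% against 67.4%, with 8 random lists as high. All 15 combinations lay above the random interval, and did so at every distance and score threshold tried. With sites that are merely absent from at least 1 other population, 4 of them did not: H3K4me2 in LPM (96.1% against 95.2%) and all 3 marks in TGEM, with 94.7% against 94.2% for PU.1.

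**Figure D5:**
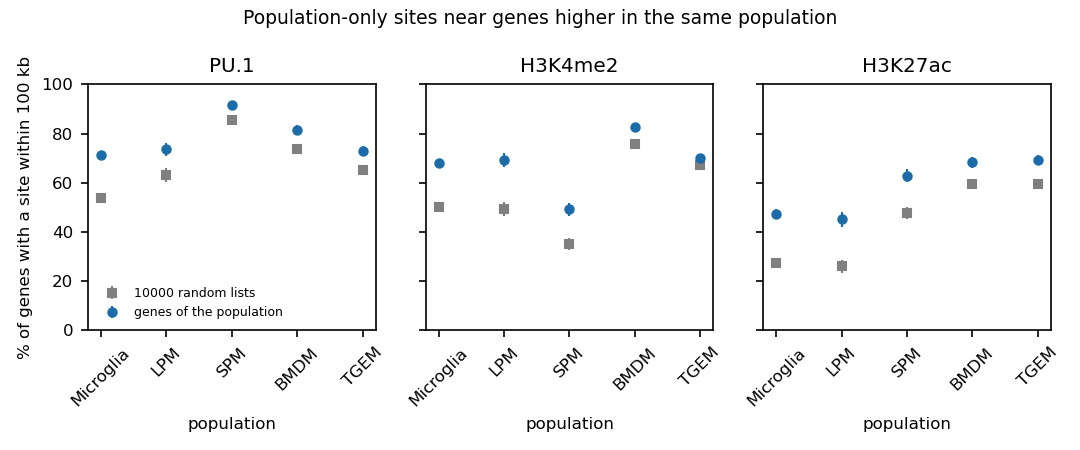
Percent of genes higher in each population with a site of that population only within 100 kb of the start, for 3 marks and 5 populations, beside the mean and interval of 10000 random lists matched on expression. Microglia PU.1 stood at 71.2% against 53.9%.

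Sites of C57BL6/J mice were looked up in the other strains (1 library each). Of PU.1 peaks shared by microglia and LPM, 22.8% (95% interval 22.4 to 23.3) were found in microglia of both NOD/ShiLtJ and SPRET/EiJ, against 4.28% (3.97 to 4.62) of microglia peaks not found in LPM, whatever the other 3 populations hold. In LPM the shares were 35.3% of shared peaks and 9.60% of peaks not found in microglia. H3K4me2 gave 37.3% and 6.23% in microglia and 42.5% and 9.47% in LPM, and H3K27ac 42.6% and 15.4% in microglia and 62.0% and 28.4% in LPM. The strain PU.1 lists are shorter, from 18633 to 36125 peaks. With lists of equal length the PU.1 shares rose to 45.9% and 20.0% in microglia and 56.0% and 31.0% in LPM, with the same order.

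In cultured LPM with M-CSF, 28624 PU.1 peaks were listed with ATRA and 9645 with DMSO, and 90.0% of the DMSO peaks were also listed with ATRA (66.1% with lists of equal length). The lowest score listed is 47.7 for DMSO and 16.0 for ATRA, so the numbers of peaks cannot be compared. Of the ATRA peaks, 84.9% overlapped a peak of freshly sorted LPM and 58.9% one of microglia. H3K4me2 lists held 1580 regions with ATRA, 1139 with DMSO, 8898 with TGFB1 and 873 with its vehicle. Of the DMSO regions 18.6% recurred with ATRA, and of the vehicle regions 62.4% recurred with TGFB1 (19.6% with lists of equal length). H3K27ac lists held 6011 and 3963 regions with ATRA and DMSO, and 73.8% of the latter recurred, while 45.9% of the vehicle regions recurred with TGFB1. At most 0.405% of the entries of a cultured list lay at transcript starts, and the reason is not given. The H3K27ac lists of TGFB1 and its vehicle hold far shorter regions than those of ATRA and DMSO and were not set against them.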

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

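The tests given here were chosen after the results were seen, except the test for B cells among the sorted SPM, whose prediction was written before its genes were measured.

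The difference between microglia and LPM was itself tested for a difference between the C57BL6/J pairs and the pairs of the other strains, over 8 libraries and 18716 genes. With limma 3 genes passed, each with an adjusted p = 0.0383, and 1723 had an unadjusted p below 0.05. Fos differed between microglia and LPM by log2 5.67 and 4.95 in the C57BL6/J pairs, -0.18 in NOD/ShiLtJ and -1.80 in SPRET/EiJ, so the C57BL6/J difference was larger by 6.30 ± 0.60 (SE). For Klf2 it was larger by 5.36 ± 0.49, from 0.20 and -0.32 in C57BL6/J against -5.89 and -4.96 in the other strains. The adhesion scaffold gene Magi1, named after its values were seen, was larger by 5.96 ± 0.51. Fos and Klf2 belong to the immediate early and stress genes, of which 18 of 18 were larger in C57BL6/J adjusted over the list alone.

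These immediate early and stress genes differed between microglia and LPM by a median log2 of 3.45 and 3.24 in C57BL6/J, 0.15 in NOD/ShiLtJ and -1.62 in SPRET/EiJ. The value of -1.62 argues against an excess over LPM that microglia hold in every preparation. Neurons among the sorted microglia are argued against as well, since the neuron genes Snap25, Syt1, Rbfox3 and Stmn2 sum to at most 50 in the C57BL6/J microglia and to 172 and 216 in the other strains. Handling of the C57BL6/J microglia before lysis may be the source, but the lower of the 2 C57BL6/J medians, 3.24, does not separate it from strain or deposited table, so these cannot be told apart. A difference of the strains themselves, which the design names, stays open and untested. Each value is microglia over LPM, so a change in the LPM libraries stays open and untested too.

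B cell genes were higher in SPM than in LPM by a median log2 of 4.01 over 8 markers in replicate 1 and 2.5 in replicate 2. The 2.5 in the deeper replicate 2 argues against low depth of replicate 1 as the cause. B cells among the sorted SPM would raise a second list of B cell genes, of which 6 of 9 measured genes were over 2 times higher in both replicates, among them Cd22, Ly6d and Spib, while Bank1, Cr2 and Bach2 were not. This falls between the 80% set for B cells and the bound set against them, so B cells and expression by SPM cannot be told apart. LPM express part of these genes too, with Bank1 at 1903 and 4991 in LPM.

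The strain table lists 0 reads on 1047 X genes and 48 Y genes in all 4 libraries. Low depth of the strain libraries is argued against, because the shallowest other library with introns counted, SPM replicate 1, has 2.73% of its reads on X. The PU.1 lists of the same strains hold at least 239 peaks on X, so the values are consistent with a deposited strain table that leaves out X and Y genes. No biological explanation was tested. X and Y genes of these strains were therefore left out of the strain fits.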

How the results depend on the processing

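The edgeR test on recovered reads, the tests with X and Y genes, the comparison of SPRET/EiJ with NOD/ShiLtJ and the other splits of the samples were chosen after the values were seen. No named gene or fixed list reversed under any alternative, but the balance of higher and lower genes did in 7 comparisons. It went from 2440 and 3501 to 3014 and 2679 with edgeR in microglia, from 1683 and 1170 to 229 and 278 without BMDM replicate 2 in BMDM, from 2455 and 2854 to 2938 and 2690 with quantile normalization and 2943 and 2411 with edgeR in TGEM (and without microglia replicate 1 or TGEM replicate 1), and from 22 and 34 to 9 and 0 with no filter for SPRET/EiJ against NOD/ShiLtJ. It went from 549 and 933 to 527 and 271 with pseudocount 5 in cultured microglia, from 28 and 126 to 16 and 10 with quantile normalization and 10 and 5 with edgeR for IL-34, and from 489 and 544 to 517 and 455, 511 and 442, and 632 and 516 with quantile normalization, edgeR and pooled vehicles for TGFB1 (and with no filter or without each of IL-34 with DMSO, M-CSF with TGFB1 and M-CSF with the TGFB1 vehicle). The order of populations by PU.1 peaks found in no other also turned with lists of equal length (28.2% in microglia and 7.83% in SPM). Of the values of named genes and fixed lists under an alternative, 9644 stayed on the same side of the threshold, 2413 no longer passed and 9 newly passed. The values that no longer passed were 1605 of 6464 with 1 library left out, 384 of 795 with no filter on low values, 105 of 757 with no replicate block, 90 of 771 with edgeR, 67 of 795 with pseudocount 0.1, 54 of 795 with quantile normalization and 36 of 91 with the estimated correlation. They were 35 of 795 with pseudocount 5, 12 of 510 with library kind as the block, 12 of 81 with only the strain table, 9 of 102 with X and Y genes and 4 of 110 with pooled vehicles.

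Counts of genes moved as follows, and the cause was not tested unless given. With no filter they were 545 in LPM, 594 in SPM, 850 in BMDM, 17 across strains, 9 for SPRET/EiJ against NOD/ShiLtJ, 10 for ATRA, 8 for TGFB1 and 0 for IL-34; in the cultured LPM the prior degrees of freedom were infinite with the filter and 0.69 without it. For IL-34 limma had 1217 genes at an unadjusted p below 0.05 with the filter. With edgeR they were 1601 in LPM, 0 for SPRET/EiJ against NOD/ShiLtJ, 255 in cultured microglia and 15 for IL-34. With the library kind as the block BMDM had 1074, and with only the strain table the strains had 1897. Pseudocount 0.1 gave 36 for SPRET/EiJ against NOD/ShiLtJ, 235 for ATRA and 58 for IL-34, and pseudocount 5 gave 798 for cultured microglia. With X and Y genes SPRET/EiJ against NOD/ShiLtJ had 36, and quantile normalization left 26 for IL-34. With no replicate block the counts were 0 for SPRET/EiJ against NOD/ShiLtJ, 154 for ATRA and 0 for IL-34, and within 1.5 times elsewhere.

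Without 1 library at a time, counts ranged from 1375 to 2787 for microglia against LPM, 1427 to 2615 in microglia, 111 to 1173 in LPM, 17 to 1428 in SPM, 229 to 1604 in BMDM and 1184 to 2722 in TGEM. They ranged from 310 to 2147 across strains, were 0 for SPRET/EiJ against NOD/ShiLtJ, and ranged from 1121 to 1263 in cultured microglia, 0 to 290 for ATRA, 2 to 947 for TGFB1 and 0 to 182 for IL-34. A group left with 1 library is assumed to vary like the others. Fewer libraries lower the residual degrees of freedom.

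With an estimated correlation the camera adjusted p became 0.0771 for microglia genes and 0.371 for LPM genes in cultured microglia, 0.934 for LPM genes with ATRA, 0.582 for microglia genes and 0.772 for LPM genes with TGFB1, and 0.871 for LPM genes with IL-34. With lists of log2 fold 3 or more, LPM genes with IL-34 had an adjusted p of 0.0525.

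Shares of sites moved with the settings, given in the order stronger entries, lists of equal length, overlap of 50%. The lists of all populations were pooled for the next shares, so a shared site counts once in each list that holds it. Of these pooled entries, those in 1 population made up 14.58% for PU.1 (11.53, 13.84 and 15.36). They made up 16.22% for H3K4me2 (9.697, 12.21 and 19.14) and 19.88% for H3K27ac (12.45, 14.26 and 22.62). The shares among distinct sites were not counted. PU.1 peaks found in both other strains made up 22.84% of shared peaks in microglia (20.85, 45.92 and 21.55) and 4.282% of microglia peaks not found in LPM (5.389, 20.03 and 3.8), 35.25% in LPM (37.47, 55.96 and 34.45) and 9.595% of LPM peaks not found in microglia (12.37, 30.96 and 8.945). In culture, 90.01% of DMSO PU.1 peaks recurred with ATRA (91.66, 66.1 and 88.45). H3K4me2 gave 18.61% for ATRA (15.72 with equal length and 16.24 with overlap of 50%) and 62.43% for TGFB1 (67.88, 19.59 and 58.99). H3K27ac gave 73.83% for ATRA (83.45 with stronger entries and 64.35 with equal length) and 45.89% for TGFB1 (49.92 with equal length and 38.7 with overlap of 50%). All 15 combinations of sites near population genes stayed above the random interval at 20 and 500 kb and with stronger entries.

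Of the 10 splits of the 6 strain libraries, 1 (the real one) gave 2967 genes and the highest other gave 0, but 10 splits are too few for a share under 0.05. For IL-34 against M-CSF, 3 of 32 splits gave as many genes as the real one, with 154 in the real and 689 in the highest other. The 2 larger splits put both ATRA libraries on one side and both TGFB1 libraries on the other, where the additive term absorbs them. What remains is IL-34 against M-CSF within DMSO and within the TGFB1 vehicle. Both splits therefore carry the ligand difference of the vehicle cultures, with 689 genes called, and do not bear on chance. Of the 8 splits with 1 library of each additive on each side, the highest other gave 113, and 8 splits are too few for a share under 0.05, so chance is not excluded.

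Depth limits low genes most in SPM replicate 1, where 1 read is worth 3.465. The alternatives written for raw counts, those of cultured against freshly sorted LPM, of each strain against C57BL6/J and of motif windows, and the polyA library added to freshly sorted microglia were not run. Using only the table of the cultures is already how cultured microglia were tested.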

Other observations

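The prediction that microglia and LPM differ less in culture was written before the cultured values were compared; the other values here were looked up after the results were seen.

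Cultured microglia and cultured LPM still differed in genes that mark their identity. Sall1 and Sall3 stood at 80.7 and 48.0 in microglia cultured with IL-34 or M-CSF, against 0.196 and 0 in LPM cultured with vehicle. Gata6, Rarb and Timd4 stood at 76.0, 49.0 and 331.8 in those LPM against 1.58, 3.49 and 0 in the microglia. P2ry12 differed less, at 129.5 in microglia and 91.2 in LPM. Gpnmb, Mmp12 and Spp1, markers of elicited macrophages, were higher in cultured microglia, at 54940, 27370 and 12700 against 8611, 4865 and 267.6.

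The hypothesis that microglia and LPM differ less in culture than when freshly sorted was tested on the genes found higher in either population. For 1412 genes higher in microglia the median log2 difference was 2.03 in the freshly sorted NOD/ShiLtJ and SPRET/EiJ libraries and 0.51 in culture, 25.1% of it. For 2002 genes higher in LPM it was -1.88 and -0.10. The share of genes with the same sign went from 92.6% to 65.3% and from 96.1% to 52.7%. The cultured value is consistent with the hypothesis, but strain, the counting of introns and an all-gene shift of 0.25 in culture differ between the sides, with 2 microglia and 4 LPM libraries in culture.

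Tbx20 stood at 6989 to 48837 in the 4 strain libraries and at most 11.4 in the 10 C57BL6/J libraries. Summed histone genes stood at 707.6 in TGEM replicate 2, 1264 in BMDM replicate 2 and 3450 to 7842 in replicate 2 of LPM and SPM and replicate 3 of microglia, against 602.9 to 2718 in the 5 polyA libraries. Xist stood at 6418 and the Y gene Ddx3y at 2.28 in BMDM replicate 1, while TGEM replicate 2 held both, at 1738 and 186.2. The deposited PU.1 lists of LPM with TGFB1 and with its vehicle are identical, with 30259 peaks.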
